A study of Schizosaccharomyces pombe with 3 samples.

How the data were processed

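Total RNA of wild type fission yeast, Schizosaccharomyces pombe, was measured on 3 Affymetrix expression arrays, 1 array per sample. Per the labels, the cells were grown in liquid YEA, a rich yeast medium, at 30 degrees. RNA was extracted with phenol, treated with DNase I and labelled with biotin. All 3 samples carry the same genotype label and formed 1 group. The labels do not say whether the arrays came from separate cultures. The p-values of single genes (limma) thus rest only on the spread between these samples, which may be technical. In addition, limma draws the variance of each gene toward a value common to all genes. Dim genes had larger SDs than bright ones, so p-values of dim genes can be too small. The p-values of sets (Fisher's exact test) compare genes or probe sets with one another and measure no spread between samples. Genes are not independent of one another, so these p-values describe the sets on these arrays only.

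The deposited values were linear signal intensities, 1 per probe set, which the authors made with MAS5 version 5.0, per the labels and the submitters' processing notes. The scaling target, scanner, probe mask and filters were not given in the sources used here. The values were found to be scaled already: the mean signal after trimming 2% at each end was 150.0 on every array, with a spread of 0.0016% against a tolerance of 5% set in advance. The intensities were therefore used as deposited and turned into log2 with no further normalization. No value was at or below 0, and no column of per-sample values was left aside. Deposited values of different arrays were not identical.

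The probe annotation that accompanied the series named genes for 5538 of the 10928 probe sets, of which 5518 had 1 gene and 20 had several. Another 166 were Affymetrix controls and 5224 had no gene in the table. Such annotation can be old, so symbols were updated through the gene identifier with a gene table of assembly ASM294v3. That table held the genes of 2914 single-gene probe sets, which gave 2896 genes after the probe sets of a gene were averaged on the log2 scale. For 3 further probe sets the identifier was retired, and these were left out. The remaining 2601 single-gene probe sets had identifiers outside the fission yeast table and fully capitalised symbols in the budding yeast style, such as PHO8 and STE20. They were taken as probe sets of another yeast, since no table stated their organism. Of 14 genes with several probe sets, 4 had probe sets that differed by over 1 on the log2 scale. The files named no genome build, so no coordinates are given, and the assembly served only for names and gene order.

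The probe sets of the other yeast gave the background. Its limit on each array was their 95th percentile of log2 signal. For each gene the limit was subtracted from the log2 signal of the same array, and the difference was tested against 0 with limma 3.58.1 (lmFit with an intercept and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over the 2896 genes and a threshold of 0.05. Agreement between arrays was described with Pearson and Spearman correlations across genes. Genes are not independent replicates, so these carry no p.

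Gene lists numbering 30 were fixed before the data were examined, together with the tests, the alternatives and the rule for named genes. Members were matched by current symbol, platform symbol or unambiguous synonym. The 27 lists with at least 3 measured members were set against all other genes with two-sided Fisher's exact tests, once for the share above background and once for the share in the top 25% of mean signal, and the 54 tests were adjusted together. A test of the bottom 25%, adjusted over the 27 lists, was added after the data were seen. The result of 1 tested list is not reported here; the list stayed in the adjustments and in the counts of lists. The median of each list was also placed among 10000 random lists of the same size. For shifts between arrays, the median over a list of 1 array minus the mean of the other two was placed among 10000 random lists matched on mean signal in 20 bins. The brightness of a probe depends on its sequence, so the order of single genes by signal, which the naming rule and the top and bottom 25% use, mixes transcript level with probe brightness. Tests against other genes were made only for sets of genes.

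The genes named in the text were leu1, ade6 and ura4, all measured mating-type markers, the 2 members of each list with the highest and the 2 with the lowest mean signal, the 10 genes with the highest mean signal, the 10 genes above background with the largest SD, and the 5 probe sets of the other yeast with the highest mean signal. Genes outside this rule are named as such where they appear.

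The alternatives were a pseudocount of 16, median centring, quantile normalization, leaving out each array in turn, background limits at the 90th and 99th percentiles, the highest probe set of a gene, leaving out shared probe sets, a filter on dim genes, calling genes above the limit in all arrays with no model, and the top 10% in place of the top 25%. Alternatives chosen after the data were seen were a limit from 59 unspiked control probe sets, the bottom 25% and 10%, and the chaperone list without ssp1.

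The fitting steps were tested on simulated data. With 200 of the 2896 genes set 1.0 above the limit on the log2 scale, 94.0% were called above, and with 200 set 0.5 above, 75.0% were called. Of 200 genes placed at the limit, 5.0% were called above and 3.5% below, and of 200 placed 1.0 below it, 96.0% were called below. For the list test, 4.6% of 500 random lists of 20 genes were called, against 100% of lists with 14 of 20 members in the top 25%. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The number of arrays, 3, limits the precision of every value.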

Results

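Gene expression was profiled in wild type fission yeast with 3 Affymetrix arrays that also carry probe sets of another yeast. Fission yeast is a unicellular model eukaryote that divides by medial fission. The strain label gave the plus mating type (h+) and the alleles leu1-32, ade6-210 and ura4-DS/E, which affect leucine, adenine and uracil biosynthesis. The 3 arrays formed 1 group, so no condition was compared with another. Over all 10928 probe sets, signal ran from 0.014 to 2363 on array 1, from 0.012 to 2353 on array 2 and from 0.010 to 2495 on array 3. The highest value on each array was that of an Affymetrix control named for cre, not of a yeast gene. The median over the 2896 fission yeast genes was 298, 302 and 296. Values after ± are SDs of log2 signal between the arrays (n = 3).

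The arrays gave close values for most genes, and the genes with the largest spread were mostly dim. Among genes above background, the 10 largest SDs belonged to spt3, mei3, nrd1, mel1, nep2, rem1, mae1, pmp3, sck2 and kei1. The value for spt3, which encodes a subunit of the SAGA coactivator, was 2.19 ± 0.63, and that for mei3, an inducer of meiosis, was 1.11 ± 0.63. The RNA-binding protein gene nrd1 gave 2.26 ± 0.60, the alpha-galactosidase gene mel1 gave 1.01 ± 0.60, nep2 gave 1.69 ± 0.60, the meiotic cyclin gene rem1 gave 1.97 ± 0.59 and the protein kinase gene sck2 gave 3.26 ± 0.55. Brighter genes in this set were pmp3, at 8.86 ± 0.56 with signals of 570, 589 and 296, and kei1, at 7.35 ± 0.53 with signals of 199, 205 and 107. For mae1, a malate transporter gene, 3.05 ± 0.57 was the mean of 3 probe sets with mean signals of 0.388, 1.76 and 1211.

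Across genes, Pearson's r was 0.9962 between arrays 1 and 2, 0.9961 between arrays 1 and 3 and 0.9946 between arrays 2 and 3, and Spearman's rho was 0.9973, 0.9959 and 0.9951. A difference of over 1 on the log2 scale was seen for 3, 2 and 6 of the 2896 genes in these pairs. The median SD of a gene was 0.110 among the 25% of genes with the lowest signal and 0.0431 among the 25% with the highest. Over the probe sets of the other yeast, r was 0.468, 0.443 and 0.443.

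Nearly all of the fission yeast genes tested gave signal above background. These were only the genes named in the probe annotation. The 5224 probe sets with no gene in it were not tested, and 39.6% of them were above the limit in all 3 arrays. By limma, 2894 of the 2896 genes were above the background limit at an adjusted p under the threshold, and the count at an unadjusted p under 0.05 was also 2894. The exceptions were ght1, a hexose transporter gene, and mug114, a gene named for meiotic up-regulation. The value of ght1 was 0.58 ± 0.59, above the limit by 0.31 (limma adjusted p = 0.1226). The value of mug114 was -1.28 ± 1.81, below the limit (limma adjusted p = 0.0257), but its log2 signal on array 2, 0.78, lay above that array's limit. The mug114 call was lost without array 3, with quantile normalization (limma adjusted p = 0.0674) and with a pseudocount of 16 (limma adjusted p = 0.2893). Without array 1, without array 3 or with a limit at the 90th percentile, ght1 was called above background. These calls lean on the variance that limma shares across genes. On array 3 the log2 signal of ght1, 0.098, lay below that array's limit, so without array 1 the arrays left lay on both sides of it. The limit was a log2 signal of 0.27, 0.31 and 0.24 on arrays 1, 2 and 3. The median gene had a mean log2 signal of 8.22, the 5th percentile was 4.51 and the 99th was 10.45.

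**Figure D1:**
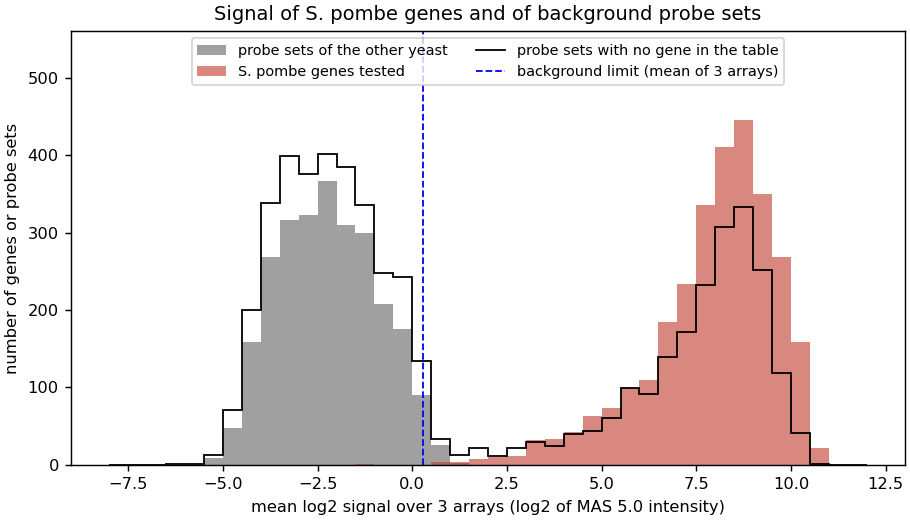
Number of fission yeast genes (red), probe sets of the other yeast (grey) and probe sets with no gene in the table (black line) by mean log2 signal over 3 arrays, with the mean background limit as a dashed line. The fission yeast genes have a median of 8.22 and the probe sets of the other yeast one of -2.28, while the probe sets with no gene fall on both sides of the limit.

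Of the 10 genes with the highest mean signal, 7 encoded ribosomal proteins and 2 encoded ubiquitin fused to a ribosomal protein. The small-subunit protein genes rps001 and rps002 gave 10.87 ± 0.02 and 10.60 ± 0.03, and the acidic ribosomal protein gene rpp202 gave 10.76 ± 0.05. Large-subunit protein genes in the set were rpl2801 at 10.70 ± 0.07, rpl2301 at 10.70 ± 0.01, rpl13 at 10.62 ± 0.09 and rpl6 at 10.60 ± 0.04. The ubiquitin fusion genes ubi3 and ubi1 gave 10.67 ± 0.02 and 10.59 ± 0.07, and cpc2, which encodes the ribosome-bound RACK1 homologue, gave 10.67 ± 0.09.

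Lists of protein synthesis, energy metabolism and protein folding genes were over-represented in the top 25% of signal. All 119 measured cytosolic ribosomal protein genes lay in it, with a median log2 signal of 10.24, and none lay in the bottom 25% (Fisher's exact test, adjusted p = 4.93e-74 and 1.12e-14). Their highest members were rps001 and rpp202 and their lowest were rpl1603 at 9.15 ± 0.01 and rps1401 at 9.21 ± 0.02. All 14 translation factor genes were in the top 25% (Fisher's exact adjusted p = 4.57e-08), from tef3, elongation factor 3, at 10.36 ± 0.04 and tef101, elongation factor 1-alpha, at 10.25 ± 0.06 to tif45 at 9.67 ± 0.03 and tif11 at 9.40 ± 0.03. Of 11 ribosome biogenesis genes, 10 were in the top 25% (Fisher's exact adjusted p = 4.66e-05), with gar1 at 10.17 ± 0.04 and cbf5 at 9.88 ± 0.06, both of the pseudouridylation complex, and with nop14 at 9.11 ± 0.06 and nog1 at 8.87 ± 0.08 lowest.

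Of 12 genes of glycolysis and ethanol fermentation, 11 were in the top 25% (Fisher's exact adjusted p = 1.41e-05), among them phosphoglycerate mutase gpm1 at 10.46 ± 0.05, aldolase fba1 at 10.41 ± 0.04 and hexokinase hxk1 at 9.11 ± 0.06. The exception was the enolase gene eno102 at 5.72 ± 0.16, which lay in the bottom 25%. Nuclear genes of the respiratory chain and ATP synthase had 26 of 33 members in the top 25% and 1 in the bottom 25% (Fisher's exact adjusted p = 1.88e-09 and 0.0068), from cytochrome c, cyc1, at 10.36 ± 0.02 and cox13 at 10.21 ± 0.04 to qcr1 at 7.43 ± 0.05 and tim18 at 6.99 ± 0.15. The proteasome, the main cytosolic protease, had 20 of 26 members in the top 25% and 0 in the bottom 25% (Fisher's exact adjusted p = 3.15e-07 and 0.0049), with rpt1 at 10.06 ± 0.05, pup2 at 9.82 ± 0.04, pre10 at 8.58 ± 0.02 and rpn11 at 7.87 ± 0.10. Chaperones had 18 of 21 in the top 25% (Fisher's exact adjusted p = 8.06e-08), with the Hsp70 genes sks2 at 10.59 ± 0.05, ssa2 at 10.34 ± 0.06 and ssa1 at 6.78 ± 0.10. The lowest member, ssp1 at 3.36 ± 0.17, matched by symbol a protein kinase gene, and without it the share was 90% (Fisher's exact adjusted p = 1.87e-08).

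Most biosynthetic genes for the nutrients of the marker alleles were also in the top 25%, and the adenine and leucine lists passed the threshold. All 10 adenine biosynthesis genes were there (Fisher's exact adjusted p = 7.02e-06), among them ade3 at 9.79 ± 0.01, ade7 at 9.75 ± 0.02, ade6 at 9.14 ± 0.01 and ade8 at 9.14 ± 0.06. All 6 measured genes of leucine and branched-chain biosynthesis were there (Fisher's exact adjusted p = 0.0013), with eca39 at 10.16 ± 0.06, ilv5 at 10.03 ± 0.06, leu3 at 9.54 ± 0.06 and ilv1 at 9.20 ± 0.03. Of 5 uracil biosynthesis genes 4 were there, which missed the threshold (Fisher's exact adjusted p = 0.0525), with ura1 at 10.03 ± 0.07, ura3 at 9.99 ± 0.06, ura4 at 9.61 ± 0.02 and ura2 at 7.58 ± 0.13. Histones had 7 of 10 members in the top 25% (Fisher's exact adjusted p = 0.0155), with histone H3 gene hht2 at 9.84 ± 0.07, H2B gene htb1 at 9.78 ± 0.08, H4 gene hhf2 at 8.78 ± 0.03 and the H2A.Z gene pht1 at 8.01 ± 0.14. The housekeeping controls had 6 of 9 (Fisher's exact adjusted p = 0.0356), with fba1, adh1 at 9.93 ± 0.06, tbp1 at 8.42 ± 0.07 and cdc2 at 7.50 ± 0.05. The proteasome, histone, adenine, leucine and housekeeping calls were not kept for the top 10% in place of the top 25%.

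Lists of meiosis and sexual differentiation genes were over-represented in the bottom 25% of signal. Of 34 meiosis and sporulation genes, 26 were in the bottom 25% and 1 in the top 25% (Fisher's exact adjusted p = 3.05e-09 and 0.0052), and the list median was 5.10. The call in the top 25% was not kept for the top 10% (Fisher's exact adjusted p = 0.8393). The extremes of the list were hrs1 at 9.85 ± 0.03 and bgs2 at 8.91 ± 0.03, and rem1 and mei3 at the values above. The entry hrs1, the 1 member in the top 25%, was matched by name only. Whether the gene matched is a meiosis gene was not checked, so that count may rest on a shared symbol. Of 200 genes named for meiotic up-regulation, 126 were in the bottom 25% and 4 in the top 25% (Fisher's exact adjusted p = 7.81e-31 and 4.16e-19), with tcg1 at 9.88 ± 0.02, mug64 at 9.87 ± 0.04, wtf3 at 0.90 ± 0.39 and mug114. Genes of nitrogen starvation and early sexual differentiation had 14 of 22 members in the bottom 25% (Fisher's exact adjusted p = 9.13e-04) and 1 in the top 25%, which missed the threshold (Fisher's exact adjusted p = 0.0772). Without array 3 this last count was 0% (Fisher's exact adjusted p = 0.0108). The ammonium transporter gene amt2 gave 9.11 ± 0.04, the mating MAP kinase gene spk1 gave 8.65 ± 0.04, isp3 gave 4.39 ± 0.04 and isp5 gave 4.08 ± 0.19. These lists share members, so their calls are not independent. Among others, bgs2 was in both meiosis lists, and isp3 was in both and in the nitrogen list. The gene inv1, outside the naming rule, was in the nitrogen list and among the glucose-repressed genes.

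Glucose-repressed genes, iron genes and MBF targets were over-represented in the bottom 25% as well. Of 9 glucose-repressed genes, 7 were there (Fisher's exact adjusted p = 0.0059), with the glycerol phosphate dehydrogenase gene gut2 at 7.26 ± 0.02, the hexose transporter gene ght4 at 7.19 ± 0.06, mae1 at 3.05 ± 0.57 and ght1. This was also the only list past the threshold in the test of the share above background, with 8 of 9 above (Fisher's exact adjusted p = 0.0258). That call rested on ght1 alone and was lost, with all 9 called above, without array 1, without array 3 or with a limit at the 90th percentile. Those calls of ght1 lean on the variance that limma shares across genes. The 3 probe sets of mae1 disagreed, with mean signals of 0.388, 1.76 and 1211, and with the highest probe set of each gene 66.7% of the list was in the bottom 25% (Fisher's exact adjusted p = 0.0297). Iron uptake and starvation genes had 7 of 10 in the bottom 25% (Fisher's exact adjusted p = 0.0116), with the iron-responsive repressor gene fep1 at 8.75 ± 0.04, the siderophore synthesis gene sib1 at 8.49 ± 0.11, and the uptake genes str3 at 5.09 ± 0.05 and fio1 at 4.28 ± 0.23. Targets of MBF, the G1/S transcription factor, had 8 of 13 there (Fisher's exact adjusted p = 0.0166), with ribonucleotide reductase genes suc22 at 9.77 ± 0.08 and cdc22 at 9.06 ± 0.06, the kinase gene mik1 at 5.44 ± 0.13 and the DNA polymerase gene pol1 at 4.65 ± 0.13. Of these bottom 25% calls, those of the meiosis lists were kept for the bottom 10%, while the nitrogen, glucose, iron and MBF calls were not, nor were the low counts of the proteasome and the respiratory chain (Fisher's exact adjusted p = 0.3087 and 0.2402). The bottom 25% test was chosen after the data were seen.

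Heterochromatin and RNAi genes were under-represented in the top 25%, with 1 of 28 (Fisher's exact adjusted p = 0.0262), a call not kept for the top 10%, and 10 of 28 were in the bottom 25% (Fisher's exact adjusted p = 0.2587). The histone deacetylase gene clr6 gave 9.27 ± 0.03, lem2 gave 8.999 ± 0.03, cid12 gave 4.28 ± 0.04 and the histone H3 lysine methyltransferase gene clr4 gave 3.83 ± 0.18. Cytoskeleton genes had 9 of 20 in the top 25% (Fisher's exact adjusted p = 0.1829), from cofilin adf1 at 9.95 ± 0.10 and profilin cdc3 at 9.83 ± 0.03 to cap1 at 6.70 ± 0.07 and the formin for3 at 4.94 ± 0.15. Ergosterol biosynthesis had 9 of 22 (Fisher's exact adjusted p = 0.2273), with erg5 at 9.996 ± 0.04, erg6 at 9.85 ± 0.05, spo9 at 6.79 ± 0.11 and erg31 at 5.56 ± 0.11. The core stress response had 8 of 26 in the top 25% and 9 in the bottom 25% (Fisher's exact adjusted p = 1 and 0.3326), with lys3 at 10.21 ± 0.07, superoxide dismutase sod1 at 10.15 ± 0.03, the phosphatase gene pyp2 at 4.90 ± 0.09 and cta3 at 3.50 ± 0.07. Copper and zinc uptake had 2 of 8 in the top 25% (Fisher's exact adjusted p = 1), with the zinc transporter gene zhf1 at 9.71 ± 0.06, adh4 at 9.21 ± 0.15, cuf1 at 7.67 ± 0.08 and metallothionein zym1 at 6.73 ± 0.03. Thiamine-repressed genes had 1 of 7 in the top 25% and 4 in the bottom 25% (Fisher's exact adjusted p = 1 and 0.1368), with the acid phosphatase gene pho4 at 9.34 ± 0.04, thi4 at 8.57 ± 0.05, bsu1 at 6.02 ± 0.06 and nmt1 at 3.52 ± 0.06.

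In each list tested, the count above background adjusted over the list alone equalled that over all genes, such as 119 of 119 for ribosomal proteins and 199 of 200 for the genes named for meiotic up-regulation. Lists with under 3 measured members were not tested. These were the phosphate-starvation genes, with vtc4 at 9.16 ± 0.02 and gde1 at 8.27 ± 0.14, the subtelomeric genes, with tlh2 at 5.52 ± 0.05, and the mitochondrially encoded proteins with 0 members. The 4 probe sets of tlh2, a helicase gene next to a telomere, had mean signals of 4.23, 41.5, 152 and 170.

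**Figure D2:**
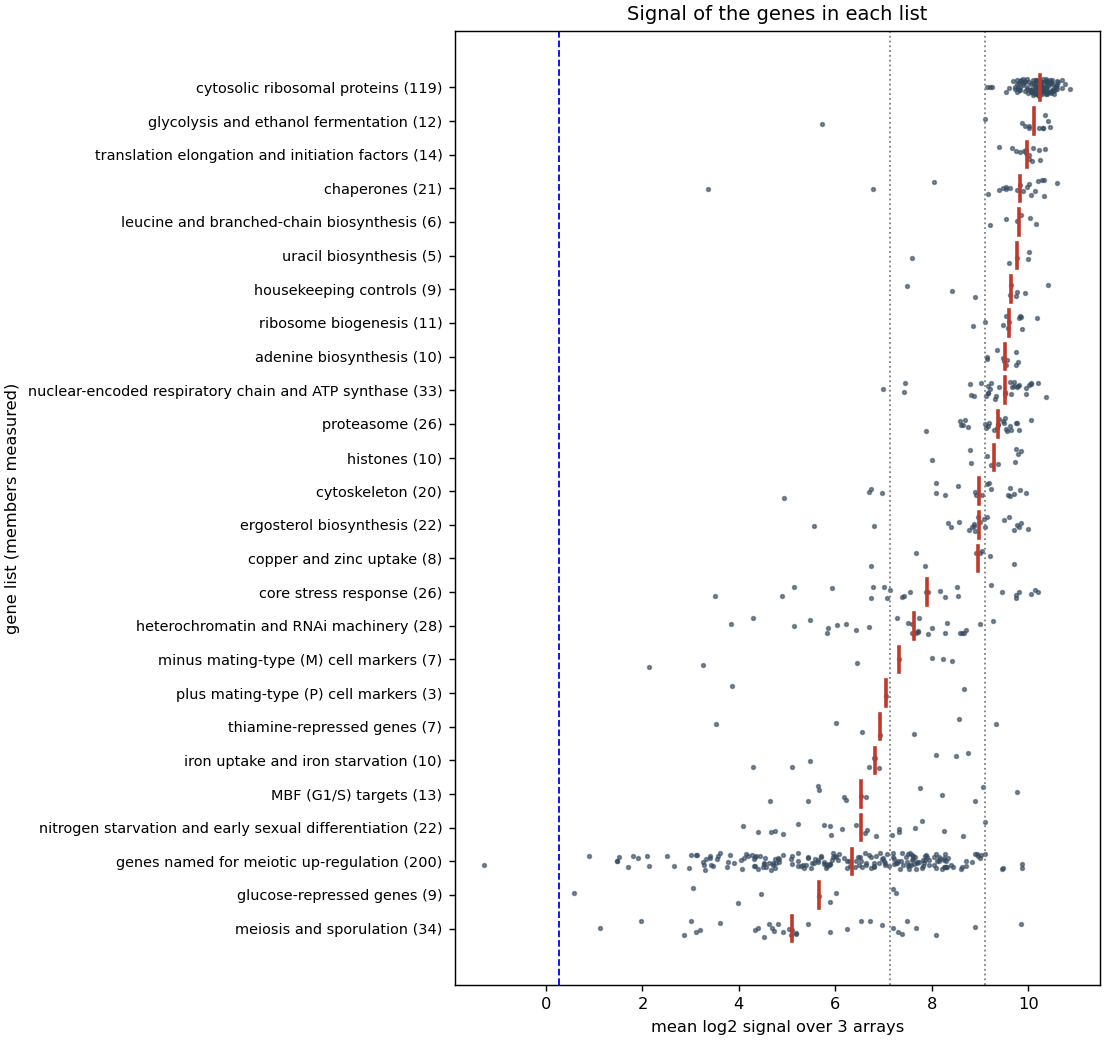
Mean log2 signal over 3 arrays of every measured member (points) of 26 tested lists, with the list median as a red bar, the quartiles of all genes tested as dotted lines and the mean background limit as a dashed line. The 119 ribosomal protein genes have the highest median, 10.24, and the 34 meiosis and sporulation genes the lowest, 5.10.

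The genes of the marker alleles in the strain label were all well above background. Values were 9.86 ± 0.09 for leu1, 9.14 ± 0.01 for ade6 and 9.61 ± 0.02 for ura4. The label ura4-DS/E names an altered ura4, and 3 control probe sets along ura4 gave mean signals of 354 at the 5' end, 814 in the middle and 868 at the 3' end. The mean log2 ratio of 3' over 5' signal was 1.295 for ura4, near the median of 1.377 over the control transcripts. A lower 5' signal was thus not particular to ura4. The positions of the probe sets relative to the altered part of ura4 were not known here, and a probe set outside that part checks nothing.

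All 10 measured mating-type markers were above background by limma, as were 2894 of the 2896 genes tested. Among P-cell markers, which act in plus cells, the pheromone gene map2 gave 3.86 ± 0.08, map4 gave 7.05 ± 0.06 and the M-factor receptor gene map3 gave 8.68 ± 0.02. Among M-cell markers, which act in minus cells, the M-factor genes mfm2, mfm1 and mfm3 gave 2.14 ± 0.20, 3.25 ± 0.27 and 7.33 ± 0.08. The protease gene sxa2 gave 6.46 ± 0.22, the pheromone exporter gene mam1 gave 8.01 ± 0.06, the agglutinin gene mam3 gave 8.23 ± 0.03 and the P-factor receptor gene mam2 gave 8.42 ± 0.04. In the top 25% were 0 of the 3 P markers and 0 of the 7 M markers (Fisher's exact adjusted p = 1 and 0.4447), and in the bottom 25% 2 and 3 (Fisher's exact adjusted p = 0.2219 and 0.4067). The mating-type genes at mat1 were not analysed here.

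**Figure D3:**
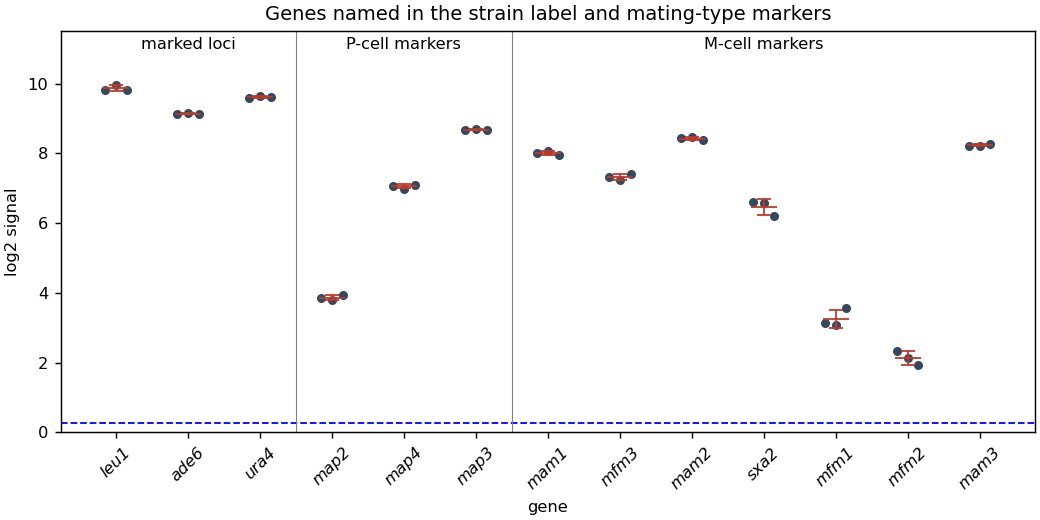
Log2 signal on each of the 3 arrays (points) with mean and SD (red) for the genes of the strain label and the P-cell and M-cell markers, with the mean background limit as a dashed line. All 13 genes lie above the limit, from 2.14 for mfm2 to 9.86 for leu1.

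Gene lists kept nearly the same level from array to array. Of 81 medians of 1 array against the other two, 4 lay outside the central 95% of matched random lists, where 4.05 would by chance. All 4 were of array 1: the translation factors at -0.05, glycolysis and ethanol fermentation at 0.01, the histones at 0.04 and the genes named for meiotic up-regulation at -0.004. No test of single genes was run for 1 array against the other two.

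Single genes stood apart on array 3. Of 2517 genes with a mean log2 signal over 6, 15 were lower on array 3 than the mean of the other two by over 0.5 and 0 were higher. On arrays 1 and 2, 0 genes were lower and 2 each were higher. The 15 genes, chosen after their values were seen, included pmp3 with -0.97, kei1 with -0.92, the translocon gene sec61 with -0.76 and the F-box protein gene pop2 with -0.74. Their median was -0.61 and 2 of the 15 belonged to any list. The log2 signals of sec61 were 7.69, 8.19 and 7.19 on arrays 1, 2 and 3. For this gene array 2 was thus as far above the others as array 3 was below. The counts of the arrays are not separate. Among these 15, sec61 and pmp3 were also counted as higher on array 2, and mug65 as higher on array 1.

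**Figure D4:**
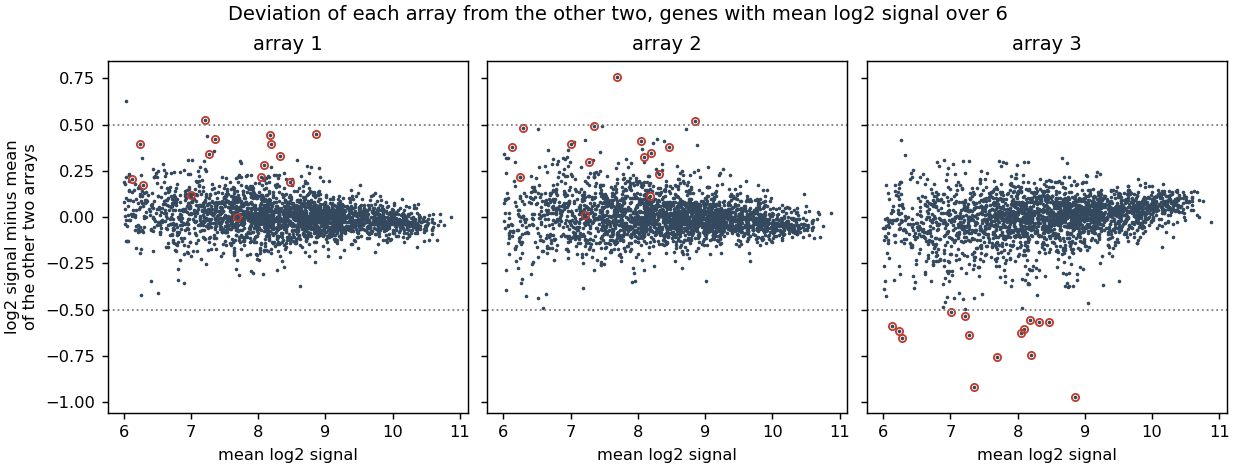
Log2 signal of each array minus the mean of the other two against mean log2 signal, for the 2517 genes with a mean over 6, with dotted lines at 0.5 either side of 0. The 15 genes circled in red lie below the lower line on array 3, and 0 genes lie above the upper line there.

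Probe sets of the other yeast had a median log2 signal of -2.28. The limit was their own 95th percentile, so at most 5% could lie above it on any array, and 20 of 2601 were above it in all 3 arrays. The 5 with the highest mean log2 signal were TPI1 at 1.31 ± 0.08, VMA4 at 1.10 ± 0.19, HHF1 at 0.93 ± 0.33, ERV25 at 0.91 ± 0.36 and LCB2 at 0.88 ± 0.14. TPI1 encodes triose phosphate isomerase and HHF1 encodes histone H4. Of 40 probe sets for highly conserved proteins, 2 were above the limit, against 18 of 2561 others (odds ratio 7.44, Fisher's exact p = 0.0368). This difference was not kept when any 1 array was left out, with odds ratios of 3.08, 3.69 and 3.32 without arrays 1, 2 and 3 (Fisher's exact p = 0.1512, 0.1147 and 0.1353), nor with a limit at the 90th or 99th percentile.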

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

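All tests of explanations for array 3 in this part were chosen after the result was seen.

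Signal was found in probe sets that entered no comparison. Of the 5224 probe sets with no gene in the table, 2070 (39.6%) were above the background limit in all 3 arrays, against 0.769% of the probe sets of the other yeast. A control probe set named for the 5' end of the 18S rRNA of Saccharomyces cerevisiae had a mean signal of 898 ± 28.4 (SD, n = 3). The control named for the 5.8S rRNA of the same species had a mean signal of 767 ± 24.5 (SD, n = 3). Others named for rRNA of that species were dimmer, with mean signals of 28.5 and 19.4 for the middle and 3' end of the 18S rRNA and 0.744, 9.81 and 27.9 for the 5' end, middle and 3' end of the 25S rRNA. Controls for 18S and 25S rRNA that name no species ran from 0.191 to 1101. The fission yeast controls for the 18S 5' end and the 5.8S rRNA had mean signals of 1012 and 842. Whether fission yeast rRNA bound to the controls of the other species was not tested.

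On array 3, 15 genes with a mean log2 signal over 6 were lower by over 0.5 than the mean of the other two arrays, with a median of -0.61. A signal-dependent difference in scaling is argued against as the whole cause, since the median of the same 15 genes was -0.58 after quantile normalization. Counted anew on those values, 13 genes were lower by over 0.5. Whether these 13 were all among the 15 is not shown here. A stronger loss of 5' ends on array 3 may contribute and stays open. Over 7 control transcripts, the median log2 ratio of 5' over 3' signal on array 3 differed from the others by -0.09. This was short of the 0.5 that would account for the pattern. GPD3 was furthest, at a 3' over 5' difference of 0.33. Its 3' control was a shared probe set and its 5' control was not, so its ratio mixes probe sets of different kinds. The position of the probe sets of the 15 genes along their transcripts was not used here. No biological explanation was tested, because the labels give 1 group.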

How the results depend on the processing

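Added after the data were seen were the limit from unspiked controls, the bottom 25% and 10%, and the chaperones without ssp1. Of values that answer a comparison, 615 stayed on the same side, while 21 were lost or fell by over 1.5 times, 7 reversed, 1 was gained and 1 moved. Of single genes, 1138 stayed, 9 calls were lost, 3 gained and 2 reversed. No paired analysis was possible because there is only 1 group. Median centring shifts a whole array and its limit alike, so it tests nothing about genes above background. It also leaves the order of genes by mean signal unchanged, as does another background limit. Counts in the top 25% could not move under these settings, nor those of other lists when ssp1 left the chaperones. Such values are among the 615, so that number overstates how much was put to a test. The count above background under the limit from unspiked controls was 2895.

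With the top 10%, 7 lists passed in place of 14. The shares were 7.69% for the proteasome, 10% for histones and 10% for adenine biosynthesis, all at or below the share of all genes, then 50% for leucine and branched-chain biosynthesis, 2.94% for meiosis and sporulation, 0% for heterochromatin and 22.2% for housekeeping controls. With the bottom 10%, 3 lists passed in place of 10. The shares were 0% for the proteasome and the respiratory chain, 30.0% for iron, 44.4% for glucose-repressed genes, 27.3% for nitrogen starvation and 15.4% for MBF. A smaller share leaves fewer genes to count.

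The lowest Pearson's r was 0.9959 with a pseudocount of 16. Leaving out 1 array gave 0% to 4.55% of nitrogen starvation genes in the top 25%, the 0% without array 3. It gave 2 list medians outside the central range for each array left out, from fewer medians. For conserved genes of the other yeast the odds ratio ran from 3.08 to 3.69 without 1 array, and was 2.59 with the 90th and 0 with the 99th percentile limit. The share of glucose-repressed genes above background was 88.9% to 100% without 1 array, with the call lost without array 1 or array 3. It was 100% with the 90th percentile limit, and 88.9% with the 99th or the pseudocount, where the call was lost too. For ght1, the difference from the limit ran from -0.000966 without array 2 to 0.53 without array 3, and was -0.22 with the 99th and 0.63 with the 90th percentile limit, where it was called above. For mug114 the call was lost without array 3, at -0.90, with quantile normalization, at -1.55, and with the pseudocount. The calls of mei3, mel1 and wtf3 were lost with the 99th percentile limit and with the pseudocount. The cause of these changes was not tested.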

Other observations

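The tests of chromosome ends were planned before their result was seen, and the test of M-cell markers was chosen after it.

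Measured genes close to the ends of chromosomes I and II were over-represented in the bottom 25% of signal. Among the 50 outermost protein-coding genes of each end of chromosomes I and II, in the gene order of ASM294v3, 48 were measured and 21 of these (43.8%) lay in the bottom 25%, against 513 of 2244 (22.9%) of the genes further in (odds ratio 2.62, Fisher's exact p = 0.0016, or 0.0047 adjusted over the 5 tests of chromosome ends). The next 50 genes of each end, which were not counted among these 2244, had 22 of 106 against the same 2244 (20.8%, Fisher's exact p = 0.7221). Most of the outermost genes were thus not measured, and fewer of them were than of the next 50 of each end. On chromosome III, 15 of 39 (38.5%) were in the bottom 25% against 134 of 406 (33.0%, Fisher's exact p = 0.4829). The members, chosen after their values were seen, included mel1 at 1.01 ± 0.60, the hexose transporter genes ght7 at 3.95 ± 0.06 and ght3 at 5.65 ± 0.04, and the galactose genes gal10 at 5.97 ± 0.18 and gal7 at 6.74 ± 0.08 (SD, n = 3). Others were str3 at 5.09 ± 0.05 and frp1 at 6.91 ± 0.15, and 9 of the 21 belonged to a gene list.

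Only 3 of the 48 outermost genes were in the meiosis lists, too few to be the whole cause. Without them the share was 40.0%, against 19.8% (Fisher's exact p = 0.0021). Taking out 3 genes could give no lower share, so this outcome was nearly fixed in advance. Meiosis genes outside the lists were not examined. Near-identical copies that share a probe set were too few to be the whole cause too, since leaving them out removed only 1 of the 48 outermost genes. Without it the share was 42.6%, against 22.9% (Fisher's exact p = 0.0028), again the lowest share that the removal could give. Copies with probe sets of their own were not examined. Whether these genes are low because of where they lie or because of what they encode was not tested and stays open.

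All 7 M-cell markers gave signal in a strain labelled plus, as did nearly all genes tested. Cells of the opposite mating type in the culture could add such signal, but this stays open: the median M marker lay at percentile 28.2 of the genes tested, below the median gene and above background. What keeps it open is that 2894 of the 2896 genes were above background, so for these markers that outcome could hardly differ. Probe brightness also differs between probe sets, and no minus strain was among the samples.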
